A study of Mus musculus with 8 samples.

How the data were processed

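Hi-C, which counts pairs of DNA segments joined in the same nucleus, was carried out on mouse embryonic stem cells after MboI digestion, per the labels' protocols. The labels give 8 libraries in 4 groups of 2: wildtype cells of strain 129S6/SvEvTac, cells of that strain without Snf2h (Snf2h ko), cells labelled Brg1fl, of another strain and with a wildtype genotype label, and Brg1 ko cells. Groups and replicate numbers were taken from the sample titles. Per the labels' growth protocol, the Snf2h ko cells were grown on feeder cells for at least their first passages after thawing, and the other lines on gelatin. The labels do not say that the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

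Per the submitters' processing notes, HiC-Pro 2.10 and bcl2fastq 2.17 were used with genome build GRCm38 (mm10). The deposited signal of each library is a contact value between bins of 150 kb after iterative matrix balancing, which gives all bins equal totals. Each deposited bin list (unit: other) holds the running number of each of 18181 bins with its chromosome, start and end. Aligner settings and read filters are not given in the sources used here. Balanced totals differ between libraries, so values were compared only after scaling within a library, as described for each measure.

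Balancing hides depth, so each balanced value was divided into a whole number of contact pairs and a bias for each of its bins. Between 99.93% and 99.97% of low values came out whole within a tolerance of 0.02 in each library. The recovered depth was 163 and 142 M pairs in the wildtype libraries, 140 and 136 M in Snf2h ko, 134 and 90.1 M in Brg1fl, and 107 and 116 M in Brg1 ko. Replicates of a group were not duplicates: recovered counts over bins differed with a chi-square per degree of freedom of 174 to 224. The recovered pairs served for depth, for raw coverage per chromosome, and for an alternative in which every library was thinned to about 90.0 M pairs.

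The analysis used 17054 bins with data in every library on 20 chromosomes (19 autosomes and X). The insulation score of a bin is the mean contact value in the diamond between the 3 bins on either side, as log2 of its ratio to the mean of that chromosome in that library. Low insulation scores mark domain boundaries, since few contacts pass over them. Boundaries were local minima of the mean profile of all 8 libraries with a strength of at least 0.2, where strength is the insulation of the highest flanking bins within 5 bins minus that at the boundary. Compartments A and B, the gene-rich and gene-poor sides of the long-range contact pattern, came from the first eigenvector of the mean observed over expected map, signed by gene density. The compartment score is log2 of mean observed over expected contact with A bins over that with B bins on the same chromosome at 1.5 Mb or more. Compartment strength is log2 of (A-A times B-B) over (A-B squared), from the 20% of bins at each end of the eigenvector. Contacts were also divided into those between chromosomes and, within chromosomes, 5 distance classes, per chromosome, which gave 120 features.

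Genes were placed by the annotation of the same build. The annotation table used here lists no strand, so the bin of a gene's midpoint stands in place of the bin of its transcription start. There were 17 fixed gene lists: pluripotency, epiblast and primed state, Hox clusters, developmental Polycomb targets, REST-bound neuronal genes, clustered protocadherins, olfactory receptors, vomeronasal receptors, zinc finger gene clusters, replication-dependent histone clusters, ribosomal proteins, imprinted genes, 2-cell stage genes, fibroblast markers for feeder cells, primitive endoderm and trophectoderm markers, architectural and remodelling factors, and the X inactivation centre. For each list with at least 5 bins, the mean observed over expected contact of each bin with the other bins of the list was taken between chromosomes and, within chromosomes, at over 3 Mb, as log2 after adding 0.1. The same was done for the 5 Mb at the start of each chromosome, next to the centromere, and the 5 Mb at its far end. List values were also set against 1000 random sets of bins with the same chromosomes and compartments.

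Every measure was tested with limma 3.58.1 (lmFit, contrasts.fit and eBayes) in R 4.3.3, with a mean per group and one estimate of the spread from all 8 libraries. Adjusted p-values are Benjamini-Hochberg values, and calls are at adjusted p under 0.05. For compartment strength limma pooled the spread fully over chromosomes. Its calls per chromosome thus treat chromosomes as independent, which those of one library are not. The contrasts were Snf2h ko minus wildtype, Brg1 ko minus Brg1fl, the difference of these contrasts, and Brg1fl minus wildtype. Shifts of gene lists were tested with limma's camera with an estimated correlation, and contacts among the bins of a list with limma's fry, which tests whether the bins of a list move one way on balance. Genome-wide means were tested with exact two-sided permutation of 2 libraries against 2, where the smallest possible p is 0.333. The self-test on simulated data, seeded for Snf2h ko against wildtype over 16861 bins, called 100% of insulation changes of 0.4 (43 falls and 59 rises). Of changes of 0.2 it called 68.6% of 51 falls and 78.7% of 47 rises. Over 17054 bins it called 93.0% of 57 compartment score falls of 1.0 and 42.9% of 49 falls of 0.5. Over 3002 boundaries it called 100% of strength changes of 0.4 (52 falls and 37 rises). Of strength changes of 0.2 it called 65.1% of 43 falls and 68.1% of 47 rises.

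The measures, tests, contrasts, lists, fixed loci and the rule for named genes were chosen before the data were examined. For insulation and compartment score in each knockout, that rule names the 5 bins with the largest rise and the 5 with the largest fall among called bins, at least 5 bins apart, or those with the smallest p where too few are called. Each bin carries up to 2 of its protein-coding genes. The same rule names the 5 boundaries with the largest loss of strength, and in each called list the 3 members with the largest change, and 23 fixed loci are given whatever their values. Of the genes and bins these rules name, 3 are not reported here. Members of lists that were not called are named as examples from the 3 with the largest changes, which was decided after the values were seen. Alternatives covered the diamond width, the boundary threshold and source, the distance limits, eigenvectors per library, quantile scaling, low coverage bins, thinned and capped values, other set tests, a replicate block, only the 4 libraries of a comparison, and each library left out in turn.

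Chromosomes Y and M were left out of the comparisons because they hold too few bins for these measures. Data from the study's other assays were not used here. The deletions themselves lie below the resolution of 150 kb bins, so the labels of the knockouts could not be checked at Smarca5, which encodes Snf2h, or at Smarca4, which encodes Brg1. Scripts ran under Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, pyarrow 21.0.0 and matplotlib 3.10.9.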

Results

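The data are contact maps of 8 Hi-C libraries in bins of 150 kb on genome build GRCm38 (mm10), 2 libraries each of wildtype, Snf2h ko, Brg1fl and Brg1 ko mouse embryonic stem cells. Snf2h, encoded by Smarca5, is the ATPase of ISWI chromatin remodelling complexes, and Brg1, encoded by Smarca4, is that of SWI/SNF complexes. Recovered depth ran from 90.1 M pairs in Brg1fl replicate 2 to 163 M in wildtype replicate 1, and between 15.8% and 18.5% of pairs joined different chromosomes. Of the bins with data, 45.7% were in compartment A and 54.3% in compartment B. Raw coverage of chromosome 1 relative to Brg1fl was 1.53 in both wildtype and Snf2h ko, and that of chromosome 14 was 1.44 in wildtype and 1.49 in Snf2h ko. The other 18 chromosomes lay between 0.951 and 1.04. Errors of log2 changes are standard errors from limma.

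**Figure D1:**
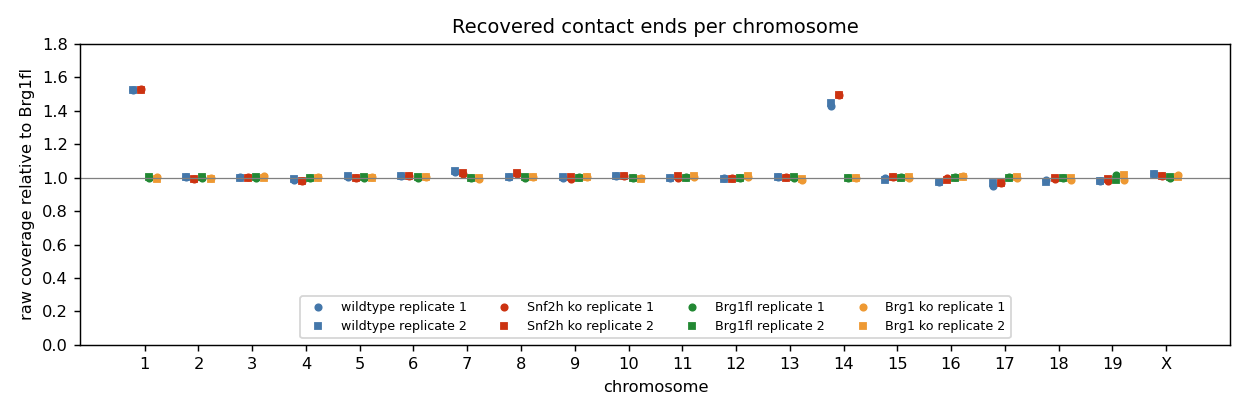
Raw coverage of each chromosome relative to Brg1fl, a ratio without units on the vertical axis, for the 8 libraries. Chromosome 1 lies at 1.53 in the wildtype and Snf2h ko libraries, and the 18 chromosomes other than 1 and 14 lie between 0.951 and 1.04.

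The comparison of Snf2h ko with wildtype asks how chromosome folding depends on Snf2h, in a study of how remodellers act on the binding of transcription factors such as CTCF, which sits at domain boundaries. Domain boundaries were weaker in Snf2h ko. Mean strength over 3003 boundaries was 0.87 ± 0.010 (SD, n = 2) in wildtype and 0.62 ± 0.0026 (SD, n = 2) in Snf2h ko in log2 units, with an exact permutation p of 0.333, the smallest that 2 against 2 libraries allow. In limma, 2211 boundaries fell and 135 rose. Quantile scaling of the scores gave 1104 falls and 811 rises and a mean change of -0.04 in place of -0.25. That scaling gives every library one distribution of scores, so it would shrink a general loss of strength whatever the cause. Boundaries were chosen on the mean profile of all 8 libraries and no set came from Snf2h ko alone, so ones gained there may be missed. The boundary at Pros1 (chromosome 16, 62850001 to 63000000), a gene for a plasma protein that limits clotting, fell by 1.13 ± 0.06, from 1.60 to 0.47 (adjusted p = 1.31e-06). The boundary at Cep290 (chromosome 10, 100500001 to 100650000), a gene of primary cilia, fell from 1.76 to 0.76 (adjusted p = 1.01e-06). The boundary at Isx and Hmgxb4 (chromosome 8, 74850001 to 75000000) fell from 1.54 to 0.57 (adjusted p = 2.61e-06), and one without a protein-coding gene (chromosome 8, 19650001 to 19800000) fell by 1.08 ± 0.10. The boundary at Ppt1 (chromosome 4, 122700001 to 122850000), a gene for a lysosomal enzyme, fell by 1.14 ± 0.27 (adjusted p = 0.00380), which a diamond of 2 bins did not call (adjusted p = 0.0611).

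Boundaries inside compartment B kept 62.0% of their wildtype strength in Snf2h ko, those inside compartment A 78.1% and those at borders between compartments 72.4%. Inside B the mean of 1074 boundaries went from 0.73 ± 0.0060 to 0.45 ± 0.0018 (SD, n = 2), with 821 falls and 34 rises. Inside A the mean of 1200 boundaries went from 0.85 ± 0.014 to 0.67 ± 0.0024, with 803 falls and 73 rises. At borders the mean of 729 boundaries went from 1.11 ± 0.012 to 0.80 ± 0.0042, with 587 falls and 28 rises. Mean insulation at boundaries went from -0.54 to -0.37 and that of flanking maxima from 0.33 to 0.26. Scores are relative to the mean of a chromosome, so a rise at boundaries alone would also lower the flanks.

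**Figure D2:**
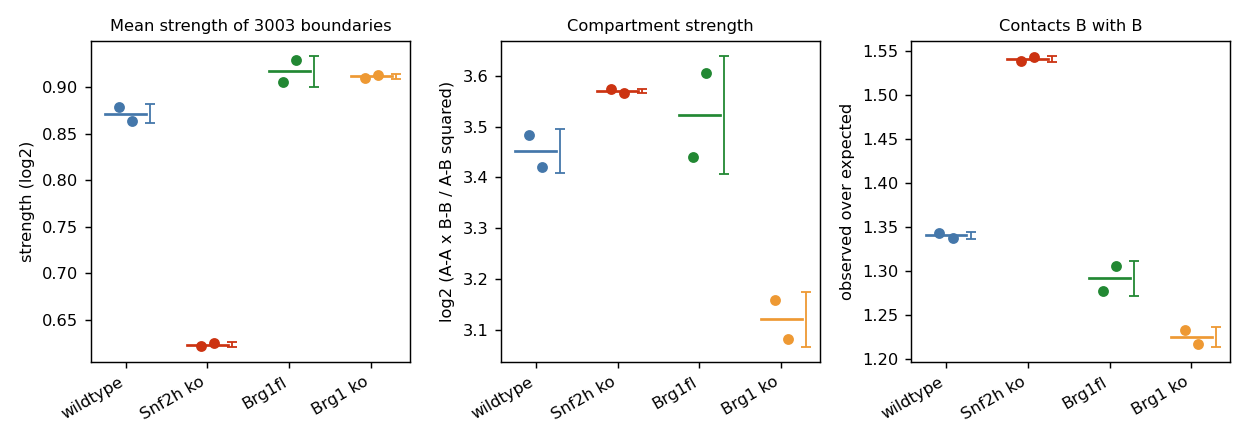
Mean boundary strength (log2), compartment strength (log2) and observed over expected contact between B bins (a ratio without units) in each library, with dots for libraries, a line for the mean of 2 and bars for the SD. Mean boundary strength lies at 0.62 in Snf2h ko and 0.87 in wildtype, and compartment strength at 3.12 in Brg1 ko and 3.52 in Brg1fl. Quantile scaling, which by construction gives every library one distribution of insulation, reduces the gap in boundary strength from -0.25 to -0.04.

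Insulation changed at 12818 of 16858 bins in Snf2h ko, with 6902 rises, where boundaries lost depth or contacts passed more freely, and 5916 falls. The bin of Cacna1b and Ehmt1 (chromosome 2, 24750001 to 24900000), of which Ehmt1 encodes a histone H3 lysine methyltransferase, rose by 0.87 ± 0.03, from -0.95 to -0.09 (adjusted p = 5.1e-06). The bin of Tcte3 and Ermard (chromosome 17, 15000001 to 15150000) rose by 0.84 ± 0.03, from -1.98 to -1.14. Ppt1 rose by 1.05 ± 0.25 (adjusted p = 0.00478), the bin on chromosome 8 at 19650001 rose by 1.06 ± 0.11, and a bin without a gene on chromosome X (54150001 to 54300000) rose by 1.00 ± 0.38. The last lost its call without wildtype replicate 2 or Snf2h ko replicate 1 (adjusted p = 0.224 for either). Of the 5 bins with the largest falls, 4 hold members of families of near-identical copies. Vmn2r40 (chromosome 7, 8850001 to 9000000) fell by 1.74 ± 0.70, Btbd35f9 (chromosome X, 34050001 to 34200000) by 1.63 ± 0.50. Vmn2r31 (chromosome 7, 7350001 to 7500000) fell by 0.99 ± 0.26, a bin without a gene (chromosome 12, 23550001 to 23700000) by 0.99 ± 0.23, and the bin of Btbd35f30 and Btbd35f5 (chromosome X, 32850001 to 33000000) by 0.89 ± 0.30. Vmn2r40 lost its call without wildtype replicate 1 (0.0619) or 2 (0.207) or Snf2h ko replicate 1 (0.0679) or 2 (0.198), and Btbd35f9 without wildtype replicate 1 (0.111) or Snf2h ko replicate 2 (0.0814). Btbd35f30 lost it without wildtype replicate 1 (0.0918) or 2 (0.0698) or Snf2h ko replicate 1 (0.182) and turned to a rise of 0.39 with a diamond of 5 bins, and Vmn2r31 turned to a rise of 0.13 with 2 bins and of 0.21 with 5 bins.

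Among 23 fixed loci, insulation rose at 10, fell at 5 and did not pass at 8 in Snf2h ko, and of 22 with a boundary within 3 bins, 5 boundaries rose, 11 fell and 6 did not pass. Of the boundaries that fell, those nearest Pou5f1, Nanog, Prdm14, Epha4 and Smarca5 turned to positive changes with quantile scaling. Zfp42, also called Rex1, a marker of naive pluripotency (gene at chromosome 8, 43295067 to 43307009), lay at a boundary in wildtype, and that boundary went from 0.56 to -0.14, a fall of 0.70 ± 0.03 (adjusted p = 1.31e-06). Its insulation rose by 0.38 ± 0.03. Insulation at Ctcf rose by 0.32 ± 0.05, at Smarca5 by 0.23 ± 0.03 and at Shh by 0.22 ± 0.03. Insulation at Pax6 fell by 0.38 ± 0.02 and at Hoxb1 by 0.27 ± 0.03, and the boundary nearest Hoxb1 rose by 0.32 ± 0.03. The boundary nearest Klf4 fell by 0.40 ± 0.05 and that nearest Shh by 0.37 ± 0.04. Insulation at Nanog rose by 0.19 ± 0.04 and at Pou5f1 by 0.18 ± 0.04, and both signs turned with quantile scaling (-0.06 and -0.04). Pou5f1 lost its call without Snf2h ko replicate 2 (adjusted p = 0.0553). Xist (+0.15, and -0.01 with quantile scaling) lost it without wildtype replicate 1 (0.137) or 2 (0.0789) or Snf2h ko replicate 1 (0.213). The boundary nearest Sox9 (-0.15) lost its call without wildtype replicate 1 (0.0568) or 2 (0.0645) or Snf2h ko replicate 1 (0.0880).

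**Figure D3:**
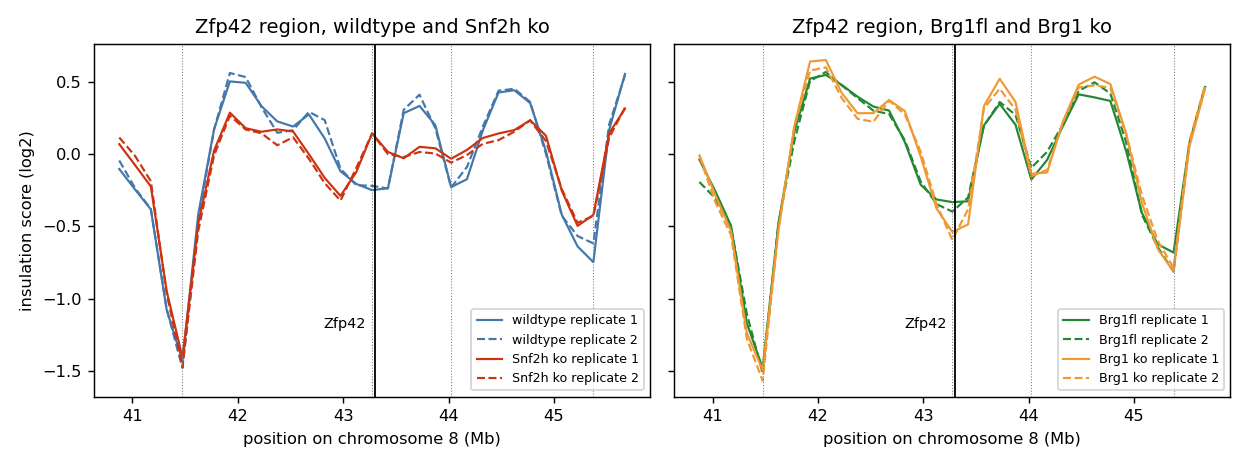
Insulation score (log2) against position on chromosome 8 (Mb) around Zfp42, with solid lines for replicate 1, dashed lines for replicate 2, dotted verticals for boundaries and a black vertical for the gene. The mean score in the Zfp42 bin is -0.24 in wildtype and 0.14 in Snf2h ko, and -0.37 in Brg1fl and -0.57 in Brg1 ko.

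Ribosomal, architectural, zinc finger, histone, pluripotency, REST-bound and primitive endoderm and trophectoderm lists had more bins that rose in insulation in Snf2h ko than fell, with and without quantile scaling. So did the imprinted, fibroblast marker, epiblast and Polycomb lists given below, and over all bins 6902 rose and 5916 fell. None of the 7 lists named first shifted against all other bins by camera with an estimated correlation (adjusted p = 0.118 to 0.246). Of 75 bins with ribosomal protein genes, 58 rose, 4 fell and 13 did not pass, with Rpl15 at +0.66 ± 0.03, Rps6 at +0.64 ± 0.04 and Rpl26 at +0.62 ± 0.05, and with quantile scaling 40 rose and 18 fell. Of 35 bins with architectural and remodelling factors, 31 rose, 1 fell and 3 did not pass (32 and 1 adjusted over the list alone), with Yy1 at +0.45 ± 0.04 and Chd1 at +0.37 ± 0.05, and with quantile scaling 19 rose and 5 fell. Of 26 bins with zinc finger gene clusters, 21 rose, 3 fell and 2 did not pass, with Zfp579 at +0.55 ± 0.06. Of 12 histone bins, 9 rose, 1 fell and 2 did not pass, with H4c8 at +0.52 ± 0.06, and with quantile scaling 5 rose and 2 fell. Of 36 pluripotency bins, 24 rose, 5 fell and 7 did not pass, with Trim28 at +0.36 ± 0.03 and Nodal at +0.35 ± 0.03. Of 44 bins with REST-bound neuronal genes, 28 rose, 3 fell and 13 did not pass, with Mapk8ip2 at +0.75 ± 0.08 and Scg3 at +0.47 ± 0.04, but with quantile scaling 17 rose and 15 fell. Of 21 primitive endoderm and trophectoderm bins, 14 rose, 1 fell and 6 did not pass, with Sox17 at +0.64 ± 0.03 and Col4a1 at +0.49 ± 0.03, and with quantile scaling 11 rose and 5 fell. Adjusted over the list alone, the counts were the same as over all bins in this paragraph except where given.

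Of 88 bins with developmental Polycomb targets, 37 rose, 19 fell and 32 did not pass (36 and 19 adjusted over the list alone), with Tal1 at +0.46 ± 0.03 and Lmx1b at +0.41 ± 0.03, and quantile scaling gave 33 rises and 28 falls. Of 7 Hox bins, 5 fell and 2 did not pass, with Hoxb13 at -0.28 ± 0.03 and Hoxa5 at -0.20 ± 0.03, and quantile scaling gave 1 rise and 6 falls. Of 17 epiblast bins, 7 rose, 6 fell and 4 did not pass, with Dnmt3a at +0.40 ± 0.03 and Mixl1 at +0.36 ± 0.03. Of 30 imprinted bins, 17 rose, 6 fell and 7 did not pass, with Mcts2 and Igf2 both at +0.42 ± 0.03. Of 24 fibroblast marker bins, 12 rose, 4 fell and 8 did not pass, with Col1a2 at +0.37 ± 0.06, and quantile scaling gave 11 rises and 8 falls. Of 5 bins of the X inactivation centre 3 rose and 2 did not pass, with Rlim at +0.48 ± 0.04, where quantile scaling gave 2 rises and 2 falls. Of 6 protocadherin bins, 3 rose, 1 fell and 2 did not pass, with Pcdhb1 at +0.40 ± 0.03 and Pcdhga1 at -0.25 ± 0.03, and with quantile scaling 3 rose and 3 fell and the mean of +0.10 turned to -0.02. Of 249 olfactory receptor bins, 73 rose, 112 fell and 64 did not pass (72 and 112 adjusted over the list alone), with Olfr1358 at +0.57 ± 0.02 and Olfr1418 at +0.49 ± 0.03. Of 127 vomeronasal receptor bins, 33 rose, 60 fell and 34 did not pass, and of 18 bins with 2-cell stage genes 3 rose, 10 fell and 5 did not pass, with Zscan4d at -0.43 ± 0.07 and Zscan4c at -0.41 ± 0.04. Counts adjusted over the list alone were the same here except where given.

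No list of the 17 shifted against all other bins in insulation or compartment score in Snf2h ko by camera with an estimated correlation, in 34 tests of which 8 had an unadjusted p under 0.05. A preset correlation called 11, fry called 29, and camera after quantile scaling called 1, the olfactory receptors' compartment score (+0.08, adjusted p = 0.0442, against a mean of -0.02 without that scaling). For insulation the estimated correlation gave adjusted p = 0.118 to ribosomal proteins and to zinc finger clusters, 0.121 to pluripotency, vomeronasal receptors and architectural factors, 0.179 to primitive endoderm and trophectoderm, 0.198 to olfactory receptors and 0.246 to REST-bound genes and histones, which the preset one had called. For compartment score it gave 0.138 to pluripotency and 0.282 to olfactory receptors, which the preset one had also called. None of the calls with a preset correlation held with an estimated correlation. In compartment score the mean of all bins moved by -0.10 and that of the olfactory receptors by -0.02, with a camera direction of up. The camera direction of vomeronasal receptors was also up, with a mean of -0.13 and a median of -0.07.

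Contacts between B bins were more frequent in Snf2h ko, and contacts between A bins less so. Observed over expected contact between B bins was 1.34 ± 0.0040 in wildtype and 1.54 ± 0.0035 in Snf2h ko (SD, n = 2), that between A bins 1.69 ± 0.0040 and 1.54 ± 0.010, and that between A and B bins 0.455 ± 0.0056 and 0.447 ± 0.00024. Compartment strength was 3.45 ± 0.044 and 3.57 ± 0.0045, a change of 0.12 (exact permutation p = 0.333) that became -0.01 when all bins were used in place of the 20% at each end. By chromosome, limma called 7 rises and 1 fall among 20, and the number called was 2 without wildtype replicate 2, 3 without Snf2h ko replicate 1, 5 without Snf2h ko replicate 2 and 13 without either Brg1fl library. Mean compartment score went from 0.90 to 0.79 in A and from -0.65 to -0.74 in B. From A to B went 335 bins and from B to A 184, 3.04% of bins. The same count between wildtype and Brg1fl, 2 lines without a knockout, was 2.98%.

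Compartment score changed at 61 of 17052 bins in Snf2h ko, with 50 falls and 11 rises, where quantile scaling gave 8 rises and no falls. Among the falls, B3glct (chromosome 5, 149700001 to 149850000) went from 0.90 to 0.06, a change of -0.84 ± 0.08, the bin of Tubb1 and Atp5e (chromosome 2, 174450001 to 174600000) changed by -0.78 ± 0.10, and that of Phactr3 and Sycp2 (chromosome 2, 178200001 to 178350000) by -0.78 ± 0.09. The bin of Mmp2 and Lpcat2 (chromosome 8, 92850001 to 93000000) changed by -0.74 ± 0.10, and a bin without a gene (chromosome 19, 27600001 to 27750000) by -0.73 ± 0.09. Among the rises, Zfp462 (chromosome 4, 55050001 to 55200000), a zinc finger gene, went from 0.57 to 1.27, a change of +0.70 ± 0.08, Pakap (chromosome 4, 57750001 to 57900000) changed by +0.71 ± 0.10, and the bin of Gtf2e2 and Rbpms (chromosome 8, 33750001 to 33900000) by +0.66 ± 0.08. Bins without genes rose by 1.14 ± 0.13 (chromosome 5, 11700001 to 11850000) and 0.85 ± 0.07 (chromosome 4, 53250001 to 53400000). Klf4, a pluripotency factor, rose by 0.55 ± 0.08 as the only fixed locus called, the Polycomb target Msx1 fell by 0.49 ± 0.07, and 2 olfactory receptor bins fell, one of them that of Olfr1378 (-0.57 ± 0.08). Adjusted p lay between 0.0450 and 0.0470 for all of these, and no call was robust to the libraries used. The number of calls was 0 without wildtype replicate 1 or without any 1 of the Brg1fl or Brg1 ko libraries, 2 without wildtype replicate 2, 3 without Snf2h ko replicate 1 and 2 without Snf2h ko replicate 2. It was 0 with thinned pairs or with only the 4 libraries of the comparison, 1178 without low coverage bins and 1332 with eigenvectors per library. Adjusted over the list alone, list members called were at most 12 falls (olfactory receptors) and 4 rises (olfactory receptors).

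Contacts in Snf2h ko moved from the shortest and the longest distances to those between. The share of contacts at 1.65 to 9.9 Mb rose on 20 of 20 chromosomes, by a mean log2 change of 0.28, and went from 11.5% to 13.9% genome-wide. Shares at 0.45 to 1.5 Mb rose on 19 chromosomes (0.11) and at 10.05 to 49.95 Mb on 12 (0.11). Shares at 50.1 Mb or more fell on all 20 chromosomes (-0.55), from 2.88% to 1.96%, and those under 0.45 Mb on all 20 (-0.11), while contacts between chromosomes fell on 3 (-0.12). Of 120 features, limma called 51 rises and 43 falls, and 60 were called without wildtype replicate 1 and 42 without either Snf2h ko library.

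**Figure D4:**
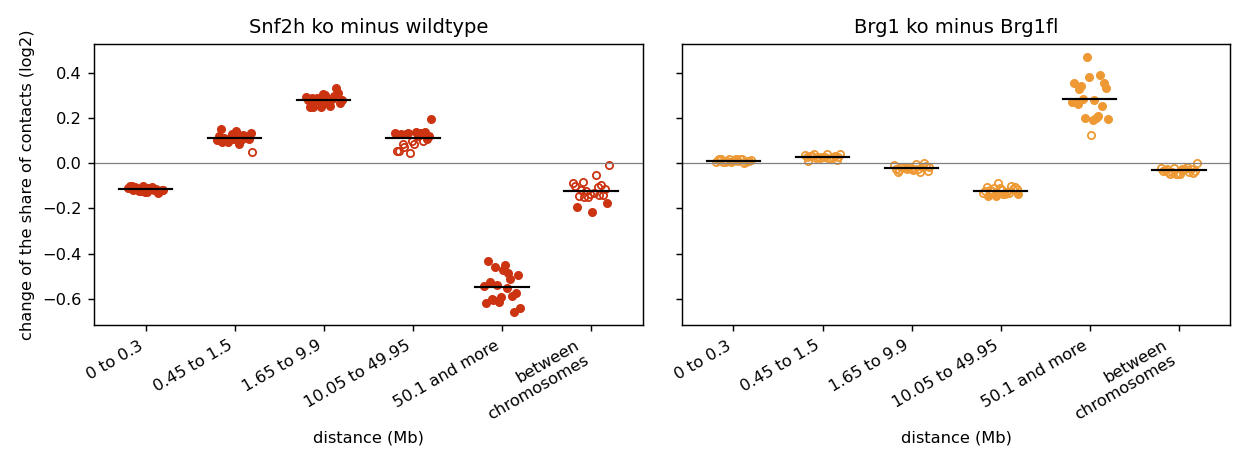
Change in the share of contacts (log2) by distance class (Mb) for each chromosome, with filled dots where adjusted p is under 0.05 and a black line for the mean over 20 chromosomes, in panels for Snf2h ko minus wildtype and Brg1 ko minus Brg1fl. The class of 50.1 Mb or more has a mean of -0.55 in Snf2h ko and 0.29 in Brg1 ko, and the class of 1.65 to 9.9 Mb a mean of 0.28 in Snf2h ko.

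Hox clusters and developmental Polycomb targets, whose bins gather in the nuclei of stem cells, had fewer contacts with each other in Snf2h ko. Observed over expected contact between Hox bins on different chromosomes was 10.5 ± 1.17 in wildtype and 3.89 ± 0.952 in Snf2h ko (SD, n = 2), a mean log2 change of -1.79 over 7 bins (fry adjusted p = 0.0175). All 7 bins were lower and in all 7 both knockout libraries lay below both wildtype libraries. Chance gives this for a single bin in 16.7% of cases per direction, but bins of a list share pairs and libraries and are not independent. The bin of Hoxd8 and Hoxd3 (chromosome 2, 74700001 to 74850000) had the largest fall, 3.52, and was listed at 0 in Snf2h ko replicate 2; without it the mean was -1.51. Hoxb13 and Hoxb9 (chromosome 11, 96150001 to 96300000) fell by 2.07, and Hoxd13 and Hoxd12 (chromosome 2, 74550001 to 74700000) by 1.7. Contact between the Hox A and Hox B clusters went from 14.5 ± 1.45 to 5.89 ± 1.67 and that between B and D from 7.26 ± 1.73 to 0.695 ± 0.982. The other pairs of clusters varied more, A and C from 11.6 ± 4.99 to 5.09 ± 3.41, B and C from 29.1 ± 4.47 to 12.2 ± 11, and A and D from 2.37 ± 3.35, with 1 wildtype library at 0, to 0 in both knockout libraries. Between C and D the libraries overlapped (5.73 ± 4.93 and 4.57 ± 2.36). The Hox call was lost without wildtype replicate 1 (0.0543) or 2 (0.105), Snf2h ko replicate 2 (0.0638) or either Brg1 ko library (0.0637), and with only the 4 libraries (0.102). The change of mean contact, -1.43, lay inside the central 95% of 1000 random sets of bins (-1.48 to 1.19), at percentile 3.

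Contact between developmental Polycomb targets on different chromosomes was 1.56 ± 0.038 in wildtype and 1.24 ± 0.053 in Snf2h ko (mean log2 change -0.29, fry adjusted p = 0.0101), and contact on the same chromosome was 1.84 ± 0.0014 and 1.35 ± 0.039 (-0.41, adjusted p = 0.000969). Between chromosomes 72 of 88 bins were lower, in 45 of which the libraries did not overlap, and within chromosomes 62 of 84, with 43. Chance gives 16.7% for a single bin, and bins of a list are not independent. Pax9 (chromosome 12, 56700001 to 56850000) fell by 1.13, Foxc2 and Foxf1 (chromosome 8, 121050001 to 121200000) by 0.96 and Msx1 (chromosome 5, 37800001 to 37950000) by 0.91 between chromosomes. Within chromosomes Six3 (chromosome 17, 85500001 to 85650000), listed at 0 in Snf2h ko replicate 1, fell by 3.37, T (chromosome 17, 8400001 to 8550000) by 2.60 and Pax5 (chromosome 4, 44550001 to 44700000) by 1.7. The call between chromosomes was lost without Snf2h ko replicate 2 (0.0506) and with only the 4 libraries (0.102), and that within chromosomes held in every alternative.

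Ends of chromosomes also changed their contacts in Snf2h ko. Contact between starts of different chromosomes, next to the centromeres, was 2.58 ± 0.10 in wildtype and 2.93 ± 0.057 in Snf2h ko (0.17, adjusted p = 0.0189), with 528 of 653 bins higher and 322 without overlap. Contact between far ends went from 2.87 ± 0.17 to 2.37 ± 0.026 between chromosomes (-0.23, adjusted p = 0.0101), with 541 of 657 bins lower and 392 without overlap. It rose within chromosomes (0.11, adjusted p = 0.00166), with 324 of 477 bins higher and 194 without overlap. In each case chance gives 16.7% for a single bin, and these bins are not independent. The call of the starts was lost without wildtype replicate 2 (0.105), Snf2h ko replicate 1 (0.0670) or 2 (0.0506) or either Brg1 ko library (0.0637), and that of far ends between chromosomes without Snf2h ko replicate 2 (0.0578). With only the 4 libraries the calls of the starts (0.122) and of the far ends between chromosomes (0.102) were lost.

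Contacts within chromosomes were called lower for 3 further lists in Snf2h ko, all of them with a weakness. Zinc finger clusters changed by -0.66 in the mean and -0.09 in the median over 19 bins (adjusted p = 0.0295), and by -0.12 over the 16 bins never listed at 0. Zfp26 and Zfp426 (chromosome 9, 20400001 to 20550000), listed at 0 in both knockout libraries, had the largest change (-5.19), before Zfp445 (-3.13) and Zfp809 (-2.27). That call was lost without Snf2h ko replicate 1 (0.114) or 2 (0.512), either Brg1fl library (0.0617) or either Brg1 ko library (0.0658). Genes of the 2-cell stage changed by -1.55 over 10 bins (adjusted p = 0.001), with Zscan4f at -4.47, Usp17ld at -3.92 and Usp17lc at -3.20. All 10 bins were listed at 0 in a knockout library and 7 in a wildtype library. Thinned pairs gave -0.74 (adjusted p = 0.774). The olfactory receptor bins of Olfr761 (+1.89), Olfr441 (+1.76) and Olfr107 (+1.73) changed most, and all were listed at 0 in wildtype replicate 2. Olfr441 was also listed at 0 in wildtype replicate 1 and Snf2h ko replicate 2. Olfactory receptors changed by -0.01 in the mean and -0.03 in the median over 232 bins (adjusted p = 0.0199). Without wildtype replicate 1 (+0.02, 0.234) or Snf2h ko replicate 1 (+0.01, 0.114) the sign turned. That call was also lost without wildtype replicate 2 (0.208), Snf2h ko replicate 2 (0.0974) or either Brg1 ko library (0.0658). With only the 4 libraries the calls of zinc finger clusters (0.234), 2-cell stage genes (0.234) and olfactory receptors (0.332) were lost. The zinc finger change of mean contact, -0.30, lay inside the central 95% of 1000 random sets (-0.40 to 0.23), at percentile 10, and that of olfactory receptors, -0.07, outside (-0.04 to 0.18), at percentile 1.1. In all, fry called 9 list contacts, but 2 with only the 4 libraries, 3 without Snf2h ko replicate 2, 5 without either Brg1 ko library and 6 without wildtype replicate 2. Among lists not called, histone bins between chromosomes went from 5.56 to 3.34 (adjusted p = 0.194) and REST-bound genes changed by -0.05 (adjusted p = 0.745).

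**Figure D5:**
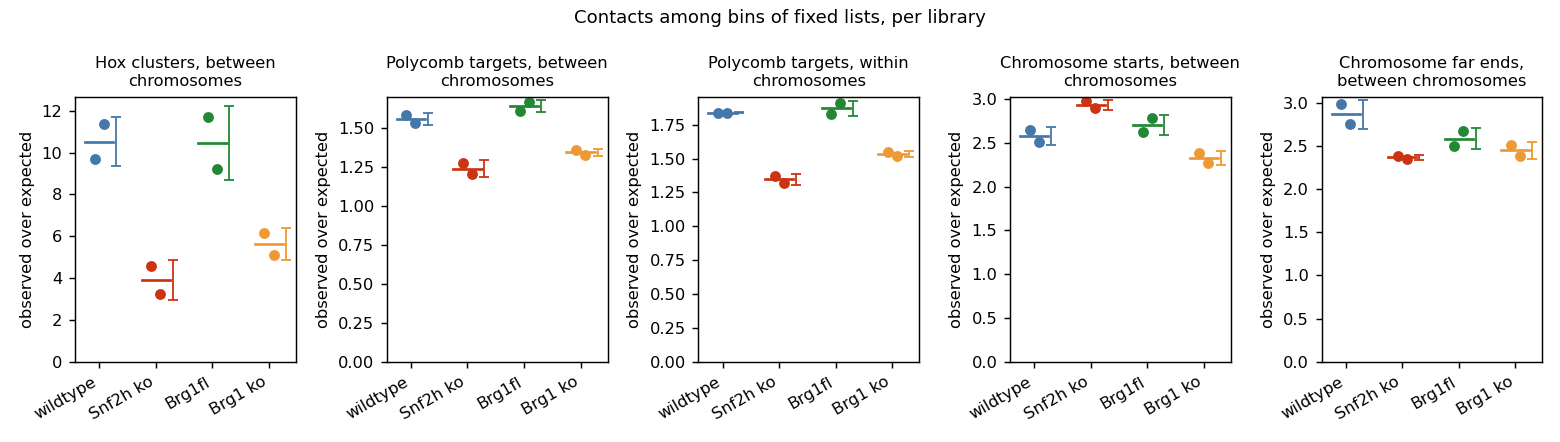
Observed over expected contact (a ratio without units, axes from 0) among bins of Hox clusters and Polycomb targets and among chromosome starts and far ends, with dots for libraries, a line for the mean of 2 and bars for the SD. Contact between Hox bins lies at 10.5 in wildtype, 3.89 in Snf2h ko, 10.4 in Brg1fl and 5.63 in Brg1 ko, of which the Brg1 ko change did not pass its test.

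The comparison of Brg1 ko with Brg1fl asks the same of Brg1. Boundary strength hardly moved in the mean, at 0.92 ± 0.017 in Brg1fl and 0.91 ± 0.0027 in Brg1 ko (SD, n = 2), with an exact permutation p of 1, while single boundaries changed both ways. In limma 257 of 3003 boundaries fell and 202 rose, with an unadjusted p under 0.05 at 987. The boundary at Zfp26 and Zfp426 (chromosome 9, 20400001 to 20550000), zinc finger genes, fell from 1.69 to 1.33 (-0.36 ± 0.05, adjusted p = 0.00762). The boundary at Smarca1 and Ocrl (chromosome X, 47850001 to 48000000), of which Smarca1 encodes the other ISWI ATPase, fell from 1.55 to 1.18 (-0.37 ± 0.06, adjusted p = 0.00939). The boundary at Tmx1 (chromosome 12, 70350001 to 70500000) fell from 0.36 to 0.01 (-0.35 ± 0.04, adjusted p = 0.00685). The boundary at Tle6 and Sirt6 (chromosome 10, 81600001 to 81750000) fell by 0.72 ± 0.18 and that at Ftsj1 and Slc38a5 (chromosome X, 8250001 to 8400000) by 0.50 ± 0.12. Tle6 lost its call without Brg1fl replicate 1 (0.0675) or 2 (0.132) or Brg1 ko replicate 1 (0.130) or 2 (0.0800), and Ftsj1 without Brg1 ko replicate 1 (0.0965) or 2 (0.0915). The number of changed boundaries was 288 without either wildtype library, 286 without either Snf2h ko library, 187 and 70 without Brg1fl replicate 1 and 2, and 102 and 124 without Brg1 ko replicate 1 and 2. By position, 88 boundaries fell and 31 rose at compartment borders, 100 fell and 101 rose inside A, and 69 fell and 70 rose inside B.

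Insulation changed at 2380 of 16858 bins in Brg1 ko, with 1074 rises and 1306 falls and an unadjusted p under 0.05 at 5472. A bin without a gene (chromosome 13, 66300001 to 66450000) fell from 0.43 to -0.06, by 0.49 ± 0.06 (adjusted p = 0.00721), and held without any 1 library. The bin of Bcl3 and Ceacam16 (chromosome 7, 19800001 to 19950000), of which Bcl3 encodes a partner of NF-kappa-B, rose by 0.78 ± 0.20, and that of Tle6 and Sirt6 by 0.60 ± 0.16. Bcl3 lost its call without either Snf2h ko library (0.0531), Brg1fl replicate 2 (0.159) or Brg1 ko replicate 1 (0.161) or 2 (0.0541). Tle6 lost it without either Snf2h ko library (0.0698), Brg1fl replicate 1 (0.0703) or 2 (0.183) or Brg1 ko replicate 1 (0.172) or 2 (0.0908). Cldn34c1 (chromosome X, 123000001 to 123150000) fell by 0.54 ± 0.11, and lost its call without Brg1fl replicate 1 (0.0701) or Brg1 ko replicate 1 (0.0829) or 2 (0.0504). In or near gene families of near-identical copies, Vmn1r116 (chromosome 7, 20850001 to 21000000) rose by 1.96 ± 0.46, Btbd35f30 by 1.46 ± 0.30 and a bin nearby without a gene (chromosome X, 33750001 to 33900000) by 2.26 ± 0.51, and Btbd35f17 (chromosome X, 4350001 to 4500000) fell by 2.26 ± 0.60. Each of these lost its call without at least 2 libraries: Vmn1r116 without Brg1fl replicate 1 (0.108) or 2 (0.0834) or Brg1 ko replicate 1 (0.101). Btbd35f30 lost it without Brg1fl replicate 1 (0.0865) or Brg1 ko replicate 1 (0.0577) or 2 (0.0917), and the bin nearby without Brg1 ko replicate 1 (0.0851) or 2 (0.103). Btbd35f17 and the bins on chromosome 14 (6600001 to 6750000, a fall of 0.59 ± 0.15) and chromosome 12 (19800001 to 19950000, a fall of 0.39 ± 0.10) each lost theirs in 7 of the 8 cases. The exceptions were Brg1 ko replicate 1, Brg1fl replicate 1 and Brg1 ko replicate 1 in turn, with adjusted p up to 0.179, 0.144 and 0.168. The number of changed bins was 1470 without either wildtype library, 1563 without either Snf2h ko library, 804 and 735 without Brg1fl replicate 1 and 2, and 652 and 640 without Brg1 ko replicate 1 and 2. With only the 4 libraries of the comparison it was 0 by limma.

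Among the 23 fixed loci, insulation rose at 1, fell at 4 and did not pass at 18 in Brg1 ko, and of 22 boundaries near them 3 rose, 3 fell and 16 did not pass. At Zfp42 the boundary rose by 0.31 ± 0.03, from 0.69 to 1.00 (adjusted p = 0.00685), and insulation fell by 0.20 ± 0.03 (adjusted p = 0.0109). Insulation fell at Xist by 0.31 ± 0.06, a call lost without Brg1fl replicate 2 (0.0649) or Brg1 ko replicate 2 (0.0502). It fell at Epha4 by 0.16 ± 0.03, lost without Brg1fl replicate 1 (0.0801) or Brg1 ko replicate 1 (0.0977) or 2 (0.0610). At Smarca4 it fell by 0.14 ± 0.03, lost without Brg1fl replicate 1 (0.0517) or 2 (0.0791) or Brg1 ko replicate 2 (0.0812). The boundary nearest Smarca5 rose by 0.16 ± 0.03, lost without Brg1fl replicate 2 (0.0773) or Brg1 ko replicate 1 (0.0586) or 2 (0.0730). The boundaries nearest Sox2 (-0.13), Myc (-0.11), Epha4 (-0.12) and H19 (+0.13) each lost their calls without any 1 of the 8 libraries, with adjusted p up to 0.107, 0.143, 0.150 and 0.111.

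Insulation changed at 14.1% of all bins in Brg1 ko. Of 75 ribosomal protein bins, 5 rose, 19 fell and 51 did not pass (7 and 26 adjusted over the list alone), with Rps10 at -0.21 ± 0.03, Rpl5 at -0.20 ± 0.02 and Rpl34 at +0.22 ± 0.04. Of 36 pluripotency bins, 1 rose, 7 fell and 28 did not pass, with Fgf4 at +0.21 ± 0.02 and Trim28 at -0.18 ± 0.03. Of 18 bins with 2-cell stage genes, 7 fell and 11 did not pass (0 and 8 adjusted over the list alone), with Tcstv1 at -0.34 ± 0.07. Of 17 epiblast bins, 1 rose, 2 fell and 14 did not pass (1 and 6 adjusted over the list alone), with Zic2 at +0.19 ± 0.03 and Cdh2 at -0.16 ± 0.02. Of 21 primitive endoderm and trophectoderm bins, 1 rose, 4 fell and 16 did not pass (1 and 7 adjusted over the list alone), with Sox7 at -0.25 ± 0.02 and Lamb1 at -0.22 ± 0.03. Of 35 bins with architectural and remodelling factors, 3 rose, 4 fell and 28 did not pass, with Smarca1 at +0.33 ± 0.04 and Wapl at -0.19 ± 0.04. Of 5 bins of the X inactivation centre, 3 fell and 2 did not pass (0 and 4 adjusted over the list alone), with Ftx at -0.23 ± 0.04. Of 44 bins with REST-bound genes, 2 rose, 5 fell and 37 did not pass (5 and 7 adjusted over the list alone), with Vgf at -0.20 ± 0.03.

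Of 249 olfactory receptor bins, 22 rose, 12 fell and 215 did not pass, with Olfr715b at +0.24 ± 0.04, and of 127 vomeronasal receptor bins 11 rose, 3 fell and 113 did not pass (8 and 3 adjusted over the list alone), with Vmn1r116 named above. Of 88 Polycomb target bins, 6 rose, 5 fell and 77 did not pass (6 and 9 adjusted over the list alone), with Gsc at +0.24 ± 0.03, Gsx2 at +0.19 ± 0.03 and a mean of 0.01 against a median of -0.0003. Of 7 Hox bins, 1 rose and 6 did not pass (4 and 0 adjusted over the list alone). Of 26 zinc finger bins, 2 rose, 3 fell and 21 did not pass (2 and 4 adjusted over the list alone), with Zfp553 at -0.27 ± 0.03, a mean of -0.005 and a median of 0.01. Of 6 protocadherin bins, 2 rose, 1 fell and 3 did not pass, with Pcdhb20 and Pcdhga1 both at +0.21. Of 12 histone bins, 1 fell, H1f0 at -0.20 ± 0.04, and 11 did not pass (2 rises and 1 fall adjusted over the list alone). Of 30 imprinted bins, 3 fell and 27 did not pass, with Ascl2 at -0.18 ± 0.03, and of 24 fibroblast marker bins 4 rose, 3 fell and 17 did not pass, with S100a4 at +0.29 ± 0.07 and Thy1 at -0.18 ± 0.03. No list shifted by camera with an estimated correlation in 34 tests (9 with an unadjusted p under 0.05, 14 called with a preset correlation, 22 by fry). For insulation the adjusted p with an estimated correlation was 0.163 for epiblast, olfactory receptors, ribosomal proteins, 2-cell stage genes, primitive endoderm and trophectoderm and the X inactivation centre, 0.240 for architectural factors and 0.294 for Hox clusters, which the preset one had called.

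Compartment strength was lower in Brg1 ko on every chromosome. It was 3.52 ± 0.12 in Brg1fl and 3.12 ± 0.055 in Brg1 ko (SD, n = 2), a change of -0.40 (SE 0.091) with an exact permutation p of 0.333, and limma called a fall on 20 of 20 chromosomes, which are not independent within a library. The change was -0.16 when all bins were used in place of the 20% at each end, with a fall on 19 chromosomes. Contact between A bins went from 1.85 ± 0.0073 to 1.75 ± 0.012, between B bins from 1.29 ± 0.020 to 1.22 ± 0.011, and between A and B bins from 0.456 ± 0.016 to 0.497 ± 0.0088. Mean compartment score went from 0.94 to 0.84 in A and from -0.60 to -0.53 in B. No bin changed compartment score by limma, with an unadjusted p under 0.05 at 3404 of 17052 bins, and eigenvectors per library gave 148 calls, 40 rises and 108 falls. Without 1 library the count was 1 (either wildtype library), 6 and 12 (Brg1fl replicate 1 and 2) and 7 and 12 (Brg1 ko replicate 1 and 2). The bins with the smallest p, all at adjusted p = 0.125, included Nrg3 (chromosome 14, 38850001 to 39000000), a neuregulin gene, at +0.75 ± 0.08 and Baz2b (chromosome 2, 60000001 to 60150000), a bromodomain gene, at -0.57 ± 0.08. Others were Lamtor3-ps (chromosome 14) at +1.00, Olfr868 at +0.62, bins without genes on chromosome X (+0.87), 14 (+0.64) and 11 (-0.68), Fam219a at -0.57 and Stard8 at -0.53. No list member was called, and adjusted over the list alone 8 Polycomb target bins fell, 2 pluripotency bins rose and 5 fell. The preset correlation had called compartment score shifts of Polycomb targets and pluripotency, which had an adjusted p of 0.118 with an estimated correlation, of olfactory and vomeronasal receptors (0.146), ribosomal proteins (0.149) and architectural factors (0.281), and the ribosomal mean of -0.08 turned to +0.05 with quantile scaling. Bins that went from A to B numbered 179, and 126 went from B to A, 1.79% of bins, against 2.98% between wildtype and Brg1fl.

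Contacts over the longest distances were more frequent in Brg1 ko. The share at 50.1 Mb or more rose on 19 of 20 chromosomes, by a mean of 0.29, and went from 2.15% to 2.59%, while that at 10.05 to 49.95 Mb fell on 4 (-0.12). Of 120 features, 19 rose and 4 fell, with an unadjusted p under 0.05 at 38, and the number called was 49 without Brg1fl replicate 2, 4 without Brg1 ko replicate 2 and 0 without Brg1 ko replicate 1.

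Developmental Polycomb targets had fewer contacts with each other in Brg1 ko. Between chromosomes observed over expected contact was 1.64 ± 0.039 in Brg1fl and 1.34 ± 0.023 in Brg1 ko (-0.24, fry adjusted p = 0.0163), and within chromosomes 1.87 and 1.54 (-0.31, adjusted p = 0.01). Between chromosomes 63 of 88 bins were lower, in 38 of which the libraries did not overlap, and within chromosomes 62 of 84, with 34. Tbx15 (chromosome 3, 99150001 to 99300000) fell by 1.13 and Sox17 (chromosome 1, 4350001 to 4500000) by 0.80 between chromosomes. Six2 (chromosome 17, 85650001 to 85800000) fell by 2.04, Dlx5 and Dlx6 (chromosome 6, 6750001 to 6900000) by 1.38 and T by 1.19 within chromosomes. The call between chromosomes was lost without Brg1fl replicate 2 (0.0531) or Brg1 ko replicate 1 (0.0881) or 2 (0.107) and with thinned pairs (0.0726), and that within chromosomes without Brg1fl replicate 1 (0.111) or 2 (0.177). With only the 4 libraries both were lost (0.107 and 0.112). Hox bins went from 10.4 ± 1.77 to 5.63 ± 0.749 with 6 of 7 lower, which did not pass (adjusted p = 0.139). Among chromosome starts 557 of 653 bins had less contact with each other, and in 384 the libraries did not overlap. Chance gives 16.7% for a single bin, and these bins are not independent. Contact between starts was 2.70 in Brg1fl and 2.33 in Brg1 ko (-0.24, adjusted p = 0.0163). That call was lost without Brg1fl replicate 2 (0.0531) or Brg1 ko replicate 1 (0.0533) or 2 (0.0660), and with only the 4 libraries (0.0725).

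Pluripotency genes also had less contact between chromosomes in Brg1 ko, 2.32 against 1.97 (-0.27, adjusted p = 0.0453), with 24 of 36 bins lower and 10 without overlap. Klf5 (chromosome 14, 99300001 to 99450000) fell by 1.26, Dppa3 (chromosome 6, 122550001 to 122700000) by 1.25 and Nr0b1 (chromosome X, 86100001 to 86250000), listed at 0 in both Brg1 ko libraries and in Brg1fl replicate 2, by 1.66. The pluripotency call was lost without any 1 library except Brg1fl replicate 1, with adjusted p of 0.167 (either wildtype library), 0.130 (either Snf2h ko library), 0.0531 (Brg1fl replicate 2), 0.0533 (Brg1 ko replicate 1) and 0.329 (Brg1 ko replicate 2), and with only the 4 libraries (0.160). The change of mean contact, -0.24, lay inside the central 95% of 1000 random sets (-0.38 to 0.31), at percentile 13.8. Olfactory receptors went from 1.11 to 1.04 between chromosomes (-0.08, adjusted p = 0.0453), with 147 of 249 bins lower and 56 without overlap, among them Olfr1126 at -1.17 and Olfr417 at -0.91, with Olfr1154 at +1.21. That call was lost without any 1 library except Brg1 ko replicate 2 and with only the 4 libraries (0.225), and the change of mean contact, -0.09, lay inside the central 95% of random sets (-0.15 to 0.13), at percentile 6.2. In all, fry called 5 list contacts, 0 with only the 4 libraries, 0 without Brg1fl replicate 2 and 2 without Brg1 ko replicate 1.

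The difference of the knockout contrasts asks whether folding changed alike in the knockouts. Each knockout was made in another line, and only the Snf2h ko cells were grown on feeder cells. Remodeller, line and culture therefore cannot be told apart in this contrast. At Zfp42 the boundary changes differed by 1.01 ± 0.05 (adjusted p = 7.62e-06), since it fell in Snf2h ko and rose in Brg1 ko, and insulation changes at Pax6 differed by 0.46 ± 0.04 and at Ctcf by 0.39 ± 0.07. Boundary strength changed differently at 2044 of 3003 boundaries, lower in Snf2h ko by comparison at 1885 and higher at 159, where quantile scaling gave 908 and 715. Insulation changed differently at 11175 of 16858 bins, compartment strength on 19 of 20 chromosomes and contact shares in 68 of 120 features. Chromosomes are not independent within a library. Compartment score differed at no bin by limma, with an unadjusted p under 0.05 at 4139. Across bins the insulation changes of the knockouts had Pearson r = -0.12 and Spearman rho = -0.16, and bins are not independent. Of 1893 bins changed in both, 691 went the same way, and 1810 would be shared if calls were independent. Falls of Polycomb contacts did not differ between the knockouts by fry (adjusted p = 0.900 between and 0.113 within chromosomes), nor did those of Hox clusters (0.380). Chromosome starts differed (0.41, adjusted p = 0.00832), as did pluripotency genes between chromosomes (0.35, adjusted p = 0.0378) and, within chromosomes, far ends (0.14, adjusted p = 0.00579) and 2-cell stage genes (-2.78, adjusted p = 0.00245). The starts lost this call without Brg1 ko replicate 1 (0.0593) or 2 (0.0550), and far ends and 2-cell stage genes without wildtype replicate 1 (0.0504 for both). Pluripotency genes lost it without any 1 library except Brg1fl replicate 2 (up to 0.108) and with thinned pairs (0.117), and 2-cell stage genes with thinned pairs (0.544).

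The lines from which the knockouts were made also differed. Between Brg1fl and wildtype, boundaries were stronger at 719 of 3003 and weaker at 226 in Brg1fl, and insulation rose at 2018 bins and fell at 2816. The share of contacts at 50.1 Mb or more was lower in Brg1fl on 19 of 20 chromosomes (-0.41), and 388 bins went from A in wildtype to B in Brg1fl and 120 from B to A. No bin differed in compartment score by limma, with an unadjusted p under 0.05 at 3738.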

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

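The depth, feeder and random ligation tests of boundary strength, and the depth and random ligation tests of compartment strength, were chosen only after the result was seen, as was the comparison of mitochondrial contact ends.

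The test of the difference between the knockout contrasts drew attention to 8 results. It cannot tell the remodeller from the line and the culture. Insulation changed differently in the 2 knockouts at 11175 bins, boundary strength at 2044 boundaries, compartment strength on 19 chromosomes and contact shares in 68 distance features. Contacts among chromosome starts between chromosomes differed by 0.41 (log2, adjusted p = 0.00832), and those among pluripotency genes between chromosomes by 0.35 (adjusted p = 0.0378). Within chromosomes, contacts among far ends differed by 0.14 (adjusted p = 0.00579) and those among 2-cell stage genes by -2.78 (adjusted p = 0.00245), the latter over 10 bins that were all listed at 0 in a Snf2h ko library. Each of these 4 list calls was lost without at least 1 library, and those of pluripotency and 2-cell stage genes also with thinned pairs (adjusted p = 0.117 and 0.544). With thinned pairs the difference was 0.37 for pluripotency genes, in place of 0.35, and -1.09 for 2-cell stage genes, in place of -2.78. Outside the comparisons, Brg1 ko replicate 2 had 221 mitochondrial contact ends per M contact ends, against 67.4 in Brg1 ko replicate 1, 75.3 and 49.9 in Brg1fl, 64.7 and 62.3 in wildtype and 57.2 and 52.0 in Snf2h ko.

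Boundary strength was lower in Snf2h ko than in wildtype, by 0.25 in the mean. Depth is argued against by a change of -0.249 with every library thinned to one number of pairs, where the balanced values gave -0.248. On observed over expected values the change was -0.225, 0.908 of the size. The diamonds at boundaries and at their flanks span the same distances, so this value could hardly differ and decides nothing on the distance trend of contacts. Feeder cells would dilute the higher coverage of chromosome 1, but Snf2h ko over wildtype was 1.00 in both libraries (0.9997 in the lower), and an even background of random ligation would raise the share of contacts between chromosomes by 76.2 to 78.1 points, where the largest rise was -0.418 points, a fall. Quantile scaling, which gives all libraries one distribution of insulation, left a mean change of -0.0360. That loss of Snf2h lowers boundary strength stays a hypothesis, found and tested on the same libraries, and the feeder cells on which the Snf2h ko cells alone were grown stay open beside it as a difference in culture.

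Developmental Polycomb targets had fewer contacts with each other between chromosomes in both knockouts, by 0.29 in Snf2h ko and 0.24 in Brg1 ko. With thinned pairs 88.8% of the fall was left in Snf2h ko and 98.1% in Brg1 ko, which argues against depth as the source of the fall. The Brg1 ko call ended there (adjusted p = 0.0726, and 0.0154 to 0.107 over all alternatives) with a change of -0.24 ± 0.02 before and -0.24 ± 0.04 after (standard error between libraries), since the SD of a bin within groups went from 0.31 to 0.38. The change lay at percentile 0.2 of 1000 random sets with the same chromosomes and compartments in each knockout. Those sets were not matched on their level of contact, so they cannot decide on a general loss of contrast between chromosomes. Fewer contacts among Polycomb targets without either remodeller stays a hypothesis, on 2 libraries per group and with the Brg1 ko call lost at lower depth.

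Compartment strength was lower in Brg1 ko than in Brg1fl, by 0.40 over the 20% of bins at each end and by 0.16 over all bins. Depth is argued against by a change of -0.40 with thinned pairs, 0.995 of that with balanced values. An even background of random ligation would raise the share of contacts between chromosomes by 11.1 to 15.3 points, where the largest rise over the pairings of libraries was 0.987 points. That loss of Brg1 weakens compartments stays a hypothesis, with an exact permutation p of 0.333, the smallest that 2 against 2 libraries can give.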

How the results depend on the processing

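The tests on observed over expected values and with quantile scaling for boundaries, with quantile scaling for list shifts, without chromosomes 1 and 14, without low coverage bins together with only the 4 libraries, and a count of list contacts outside their random sets were chosen after seeing the data, the first of them before its own result was seen. The percentiles among random sets themselves were planned. Of 340 comparisons of 22 counts and means with an alternative, 246 stayed within the limits set, 93 moved and 1 reversed. In Snf2h ko, 11211 to 13446 bins changed insulation and 1802 to 2624 boundaries changed strength over all alternatives. Of 794 comparisons for list contacts 709 kept their call or lack of one, 70 lost the call, 13 gained one and 2 reversed. Most of the 64 list contact results were not called in the main setting, so most of these comparisons could not lose a call. A change of sign was counted as a reversal only where the main or the alternative result was called. For list shifts 943 of 1020 were kept, 76 gained a call and 1 reversed. None of the 68 list shifts was called in the main setting, so none could lose a call. For named bins and reported fixed loci 2757 of 3171 were kept, 344 lost the call, 51 gained one and 19 reversed.

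Changed insulation in Brg1 ko, 2380 bins, became 981 with a diamond of 2 bins, 3996 with 5 bins, 1068 with quantile scaling, 1002 with thinned pairs and 0 with only the 4 libraries of the comparison. Changed boundaries in Brg1 ko, 459, became 265 with a diamond of 2 bins, 271 with quantile scaling, 139 with thinned pairs and 62 with only the 4 libraries. Changed compartment scores in Snf2h ko, 61, became 1332 with an eigenvector of each library, 1178 without low coverage bins, 25 at 30 bins or more, 8 with quantile scaling, 0 with thinned pairs and 0 with only the 4 libraries; those in Brg1 ko, 0, became 148 with eigenvectors. Chromosomes with changed compartment strength in Snf2h ko went from 8 to 15 with only the 4 libraries. List shifts, 0 in both, became 11 and 14 with the preset correlation, 29 and 22 by fry, and 1 in Snf2h ko with quantile scaling. List contacts went from 9 to 2 in Snf2h ko and from 5 to 0 in Brg1 ko with only the 4 libraries, and to 3 in Brg1 ko with capped pixels. With only the 4 libraries the spread rests on fewer samples, and thinning leaves fewer pairs; for the other settings here and below the cause was not tested.

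The mean change of boundary strength in Snf2h ko, -0.248, was -0.290 for boundaries of strength 0.5 or more and -0.237 for those of 0.1 or more. It was -0.263 with boundaries of the other line, -0.267 with those of the 2 wildtype groups, -0.268 and -0.213 with diamonds of 2 and 5 bins, -0.225 on observed over expected values and -0.0360 with quantile scaling, which by construction gives every library the same distribution of insulation. The mean change of compartment strength in Snf2h ko, 0.118, was 0.197 with 10% of bins at each end, 0.0695 with compartments of the other line and reversed to -0.00669 with all bins, and that in Brg1 ko, -0.402, was -0.161 with all bins.

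Signs that turned at single loci are given where the main or the alternative result was called. In Snf2h ko with quantile scaling they were those of insulation at Pou5f1 (-0.0415), Nanog (-0.0566), Klf4 (-0.181) and Xist (-0.0108). Boundaries that turned there were those nearest Pou5f1 (0.00702), Nanog (0.195), Prdm14 (0.132), Epha4 (0.0803) and Smarca5 (0.0338), besides the compartment shift of olfactory receptors (0.0779). With a diamond of 2 bins these were insulation at Vmn2r31 (0.128) and the boundary nearest Hoxd13 (-0.333). With 5 bins they were insulation at Vmn2r31 (0.212), Btbd35f30 (0.390) and Myc (-0.143) and the boundary nearest Nanog (0.149), and in Brg1 ko insulation at Sox2 (0.102) and the boundary nearest Myc (0.0137). The boundary nearest Hoxd13 reversed with boundaries of the other line (-0.133) and that nearest H19 with those of the 2 wildtype groups (-0.131). Of these, insulation at Klf4, Myc and Sox2, the boundaries nearest Hoxd13 and H19 and the olfactory shift were called only under the alternative. Contacts of olfactory receptors within chromosomes in Snf2h ko reversed without wildtype replicate 1 (0.0210) and without Snf2h ko replicate 1 (0.00915), with a range of -0.0354 to 0.0210 over the libraries left out.

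Leaving out each library in turn, where the lone library left in a group is assumed to vary like the other groups, gave these ranges for Snf2h ko, Brg1 ko and, where given, their difference. Bins with changed insulation numbered 11422 to 12906, 640 to 1563 and 10055 to 10758, boundaries 2103 to 2356, 70 to 288 and 1835 to 2007, and bins with changed compartment score 0 to 3 and 0 to 12. Chromosomes with changed compartment strength numbered 2 to 13, 19 to 20 and 18 to 20, distance features 42 to 113 and 0 to 49, list contacts 3 to 10, 0 to 5 and 1 to 7, and list shifts 0 to 0 in both. The mean change of boundary strength was -0.255 to -0.241 and -0.0171 to 0.00645, and that of compartment strength 0.0876 to 0.149 and -0.485 to -0.320.

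Libraries of a group share only a replicate number with those of the other groups. Deviations from the group means of equally numbered libraries correlated at 0.167 (wildtype with Snf2h ko) and -0.0786 (Brg1fl with Brg1 ko) for insulation, 0.0146 and -0.0324 for compartment score, and 0.404 and -0.0345 for boundary strength. With a replicate block, changed insulation in Brg1 ko numbered 1180, compartment score in Snf2h ko 0, and list contacts 5 in Snf2h ko, 1 in Brg1 ko and 2 for the difference, in place of 2380, 61, 9, 5 and 4. Of those 4 difference calls by fry, chromosome starts kept theirs with the block (adjusted p = 0.0335). Pluripotency genes (0.252), far ends (0.162) and 2-cell stage genes (0.156) lost theirs.

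Small changes were called only in part. The self-test called 68.6% of insulation falls and 78.7% of rises of 0.2. It called 42.9% and 35.8% of compartment score falls and rises of 0.5. Each library was simulated at its own depth, so the self-test cannot tell depth from the spread between libraries. Thinning to 90.0 M pairs moved the counts given above.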

Other observations

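Of the tests here, the split of the matched boundaries by compartment was chosen only after the result was seen.

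Median raw coverage of chromosome X was between 0.360 and 0.377 of that of the autosomes other than 1 and 14 in all 8 libraries. Contact ends on chromosome Y numbered 437 and 441 per M contact ends in wildtype, 435 and 446 in Snf2h ko, 421 and 414 in Brg1fl, and 411 and 446 in Brg1 ko.

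A first hypothesis was that boundaries at compartment borders keep more of their strength without Snf2h than boundaries inside a compartment. Over 708 pairs of boundaries matched on their strength in Brg1fl, those at borders kept 71.1% to 72.7% of their wildtype strength in Snf2h ko and those inside 71.0% to 73.0%, over the pairings of libraries. The gap was -0.0754 percentage points (-0.280 to 0.127), where the hypothesis needed at least 10, but this mean decides nothing, since it joins pairs that went opposite ways. Against boundaries inside A (404 pairs) those at borders kept less, with a gap of -7.67 points (-7.95 to -7.39), and against boundaries inside B (304 pairs) they kept more, with a gap of 11.2 points (10.7 to 11.7). Borders keeping more than boundaries inside B, but not inside A, stays a hypothesis found on these data.

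A second hypothesis was that the line of the wildtype and Snf2h ko libraries carries an extra copy of all of chromosomes 1 and 14. In windows of 20 Mb, coverage in wildtype over Brg1fl was 1.49 to 1.58 in the 10 windows of chromosome 1 and 1.25 to 1.48 in the 7 windows of chromosome 14. The hypothesis needed 1.3 to 1.7 in every window, and the lowest, 1.25, lay under that but not under the 1.2 that would have argued against it. It was the first window of chromosome 14 (1 to 19950000), and the other windows there lay at 1.42 to 1.48. On chromosome 14 an extra copy in all cells and one in part of the cells cannot be told apart, since coverage alone does not separate them and one line is set against another. Either would act on all windows alike, so the lower first window stays unexplained.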
